A study of Mus musculus with 12 samples.

How the data were processed

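RNA was sequenced from CT26 tumour tissue of 12 mouse samples in 4 groups of 3 libraries: untreated control, Complex 1, radiation, and Complex 1 with radiation (the combination). Per the labels, the material was total RNA and the libraries were made with the NEB Next Ultra RNA kit for Illumina sequencers. Per the submitters' processing notes, STAR 2.5.3a, HTSeq 2.0.1 and DESeq2 were used with mouse genome build mm39, without a statement of which step each tool did. The DESeq2 version, the strand setting of the counting, any filter, the doses and the times are not given in the sources used here. Because the strand setting is not given, reads of overlapping and antisense genes cannot be told apart.

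The deposited table holds a raw count per gene and library, as whole numbers, for 55415 entries with Ensembl gene identifiers. In the same table the authors give FPKM per gene and library, which are these counts per kilobase of exonic gene length and per mega count of the library total, rounded to 2 decimals. Recomputing FPKM from the counts and the lengths in the table gave the deposited values within 0.005 FPKM. The design fixed before the data were examined assumed FPKM alone and a limma test on log2 values. Since counts were found, edgeR was used on them, and FPKM are given only as levels. Coordinates, identifiers and symbols are those of the deposited table, in mm39. Entries without a symbol numbered 1492 and held 0.0579% to 0.0706% of the counts of a library.

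Total counts were 15.6 to 19.1 M (mega counts) per library. A count of 3 in a gene with 2 kb of exons corresponded to 0.0785 to 0.0961 FPKM, and such floors cover counting error only. The 10 genes with most counts held 4.75% to 6.21% of a library, and mitochondrial genes 1.74% to 3.13%.

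The 13668 genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested. Counts were scaled by TMM, and edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was run on a model with a mean per group and all 12 libraries, so that the groups share 1 estimate of the spread. There were 8 comparisons: 5 between pairs of groups, the effect of radiation over both levels of Complex 1, the effect of Complex 1 over both levels of radiation, and their interaction. Genes with a Benjamini-Hochberg (BH) adjusted p under 0.05 passed, and only those are said to rise or fall.

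Of 38 gene lists written before the data were examined, 32 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01, BH over the lists of a comparison). Camera asks whether a list moves relative to other genes. Beside it, the test was repeated with the correlation estimated per list (adjusted p given below after the word estimated). fry asked whether a list's genes move, on balance, in 1 direction, and members were also BH-adjusted over the list alone.

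The genes named were chosen by a rule fixed before the data were examined. In each pairwise comparison these were up to 8 genes per direction with the largest change in log2(FPKM + 1), among those that passed with no overlap between the groups, which chance gives to 10% of genes at 3 against 3. Where fewer than 8 passed, genes with the smallest p that did not pass could be added as values. The rule also took the 3 members with the smallest p of each list that camera called, 28 fixed genes (26 tested), and the 5 genes per direction with the smallest p in the main effects. Predicted genes, pseudogenes and receptor or immunoglobulin variable segments were counted but not named. Ifnb1 and Foxp3 were the fixed genes below the filter.

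Sharing of sequence between loci was computed from the transcripts of GENCODE M21 (GRCm38), which gave a value for 13495 tested genes as the percent of a gene's 31-base sequences that also occur in another locus. M21 biotypes were matched by identifier for 13499 genes. No coordinates of that build are used. Of the 227 genes named in the text or by the rule, 226 had a value and 10 had at least 50% of their sequence in another locus: mt-Co2, mt-Co3, mt-Atp6, mt-Nd3, Hspa1a, Hspa1b, Ifit3, H2-Q6, Hsp90aa1 and Hspd1. Their counts are uncertain, since the counting may have split or dropped such reads.

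The code was tested on simulated counts for radiation against control with 13668 genes: edgeR called 62% of 100 genes changed 1.5-fold and 85% of 100 genes changed 2-fold, with 6 calls among unchanged genes (3.70% of its calls). Camera called the 1 changed list and none of the unchanged ones among 32. Each simulated gene was drawn independently of the others. The run therefore cannot show how camera with its preset correlation behaves where genes of a list vary together. Alternatives fixed before the data were examined were another pseudocount (0.1 in place of 1, with limma on FPKM), no filter, median-ratio scaling, quantile normalisation, only the groups compared, a replicate block, robust estimation and leaving out each library in turn. Where leaving out 1 library ended camera's call of a list or moved its median over 1.5 times, the new median is given. For main effects, only some are given. Alternatives chosen after the data were seen were limma on FPKM, DESeq2 1.42.0, library totals as the only scaling, protein-coding nuclear genes only (11152), leaving out Complex 1 replicate 3 and radiation replicate 2 together, and removal of the length trend. KEGG pathways were also tested after the data were seen. Simulations of unchanged groups that share the same simulated controls numbered 20. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Raw reads were not used here.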

Results

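Bulk RNA sequencing measured gene expression in tumours grown in mice from CT26, a colon carcinoma line of BALB/c mice. The 12 libraries form 4 groups of 3: untreated control tumours, tumours of mice given Complex 1, tumours of mice given radiation, and tumours of mice given both, called the combination here. The series title describes the compound as a platinum complex that X-rays activate, and names DNA damage and effects on tumours outside the irradiated field. The labels give no dose or time and do not say whether a sampled tumour lay inside that field. Total counts per library ran from 15.6 to 19.1 M (mega counts), with group means of 18.4 ± 0.703 (control), 16.7 ± 1.30 (Complex 1), 18.5 ± 0.525 (radiation) and 17.1 ± 1.55 M (combination; SD, n = 3 each). Levels below are FPKM, as mean ± SD of 3 libraries. Changes are log2 fold changes ± SE from edgeR's quasi-likelihood test, with Benjamini-Hochberg (BH) adjustment over 13668 tested genes.

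Tumour libraries separated mainly by radiation along the first principal component, with Complex 1 replicate 3 above radiation replicate 2 as the exception. This component (33.3% of the variance) ran from -32.7 to -18.4 in control, -19.8 to 4.48 in Complex 1, above 0 and up to 15.7 in radiation and 23.1 to 26.8 in combination libraries, and the second held 16.9%. Pairs of libraries correlated at 0.987 to 0.992 within groups and 0.975 to 0.991 between groups (Pearson, across genes). Differences between replicates exceeded counting noise, with a chi-square per degree of freedom of at least 5.46 within groups. The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between these samples. In immune genes, a library of each of 2 groups stood apart from its group. Complex 1 replicate 3 had scores (mean log2 difference from the control mean) of 0.936 for type I interferon genes, 1.40 for interferon-gamma genes, 1.12 for T cell markers and 1.07 for cytotoxic effectors. The other Complex 1 libraries lay between -0.207 and 0.130. Radiation replicate 2 had a T cell score of -0.599, and the other radiation libraries lay at 0.969 and 1.08. Xist, the RNA that coats the inactive X chromosome, was at 0.02 FPKM in control replicate 2, with 28 counts from Y-linked genes. The other 11 libraries had 9.20 to 14.2 FPKM of Xist and at most 1 such count.

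**Figure D1:**
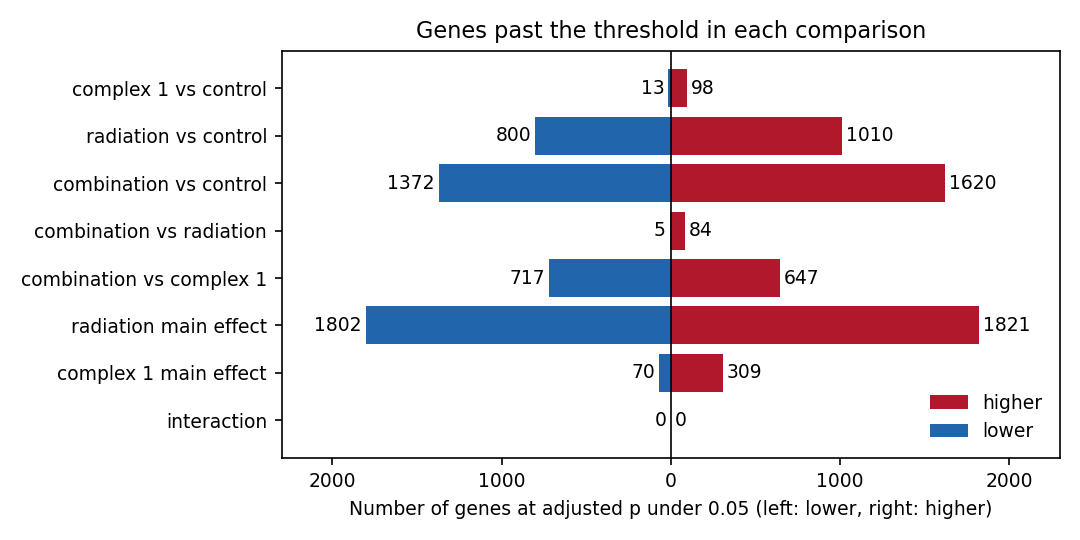
Number of genes with a higher (right) or lower (left) level at a BH-adjusted p under 0.05 in each of the 8 comparisons (edgeR quasi-likelihood, 13668 genes tested). Radiation against control has 1010 higher and 800 lower genes, Complex 1 against control 98 and 13, and the interaction none by edgeR (601 at unadjusted p under 0.05, 6 by DESeq2).

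Radiation against control shows what radiation did without the compound. Members of the p53, interferon, macrophage and cytotoxic effector lists rose, and members of the proliferation and ER stress lists fell. In total, 1010 genes rose and 800 fell (edgeR quasi-likelihood, BH), and 3885 had an unadjusted p under 0.05. At least 2-fold changes were 216 rises and 22 falls. The p53 targets gave the smallest p-values. Ccng1, which encodes cyclin G1, a direct p53 target, rose from 29.2 ± 1.55 to 72.8 ± 5.61 FPKM (log2 1.29 ± 0.08, adjusted p = 3.5e-06). Its identifier is ENSMUSG00000020326, and it lies on chromosome 11, 40639379 to 40646138 (mm39). Trp53inp1, a p53-induced nuclear protein gene, rose by 1.64 ± 0.10 (adjusted p = 3.5e-06). Eda2r, a p53-induced death receptor gene, rose by 1.02 ± 0.11 (adjusted p = 0.00042). Of the 26 p53 target genes, 12 rose (13 adjusted over the list alone) and none fell (1 did adjusted over the list alone), with a median log2 change of 0.37 (camera, adjusted p = 2.0e-08, estimated 0.021). The other p53 targets fixed for naming also rose: Mdm2, the p53 ubiquitin ligase gene, by 0.48 ± 0.06, Cdkn1a, the p21 cell cycle inhibitor gene, by 0.66 ± 0.13, Fas by 0.99 ± 0.25 and Bax by 0.50 ± 0.09.

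Genes that interferons induce rose nearly throughout their list in irradiated tumours. Of the 30 type I interferon response genes, 29 rose (30 adjusted over the list alone), with a median log2 change of 1.12 (camera, adjusted p = 6.8e-21, estimated 0.246). Mx1, an antiviral GTPase gene, rose by 2.05 ± 0.32, Ifi44 by 1.55 ± 0.26 and Ifit3 by 1.84 ± 0.36. Ifit3 shares 61.8% of its 31-base sequences with another locus, so its value is uncertain. Among the 16 genes of the list for nucleic acid sensing, 11 rose (13 adjusted over the list alone), with a median of 0.78 (camera, adjusted p = 1.3e-07, estimated 0.222). They include Tlr7 (1.14 ± 0.15), Ifih1 (1.08 ± 0.19) and Sting1 (0.58 ± 0.11). Interferon-gamma response genes had a median of 1.09, and of 23, 8 rose (19 adjusted over the list alone) (camera, adjusted p = 6.4e-09, estimated 0.391). Cxcl10 rose by 2.01 ± 0.30 and Cxcl9 by 1.17 ± 0.24; both encode chemokines that attract T cells. For antigen presentation on MHC class I, the median was 0.30 and 1 of 19 genes rose, H2-T23 by 0.81 ± 0.22 (1 adjusted over the list alone; camera, adjusted p = 0.0019, estimated 0.551). MHC class I genes were not called without radiation replicate 3 (0.22). They had 0.53 without radiation replicate 2. Ifnb1, the interferon beta gene, lay below the expression filter at 0.07 to 0.73 FPKM per library in this series.

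Immune cell markers rose in part. Macrophage and monocyte markers had 15 of 22 higher (17 adjusted over the list alone) and a median of 0.74 (camera, adjusted p = 2.0e-12, estimated 0.021). Adgre1, the F4/80 surface marker gene, rose by 1.35 ± 0.14, C1qa, a complement subunit gene of macrophages, by 0.82 ± 0.09 and Lyz2, lysozyme of myeloid cells, by 1.08 ± 0.10. In Lyz2, 32.8% of the sequence occurs in another locus, and in the neighbouring Lyz1 (2.35 ± 0.29) 34.2%. Cytotoxic lymphocyte effectors had 7 of 19 higher (9 adjusted over the list alone) and a median of 0.88 (camera, adjusted p = 4.5e-06, estimated 0.392). Gzma rose by 2.06 ± 0.32, Gzmb by 1.79 ± 0.38, Gzmc by 1.66 ± 0.48 (adjusted p = 0.039) and Prf1, perforin, by 1.53 ± 0.41. Among T cell markers, 1 of 17 rose, Lck by 0.85 ± 0.25 (0 adjusted over the list alone), with a median of 0.69 (camera, adjusted p = 0.014, estimated 0.654). Inflammatory cytokines and chemokines had 8 of 22 higher (9 adjusted over the list alone), with a median of 0.70 (camera, adjusted p = 3.4e-06, estimated 0.246). The monocyte chemokine gene Ccl8 rose from 78.8 ± 20.4 to 344 ± 60.8 FPKM (log2 2.10 ± 0.30, adjusted p = 0.0014), Ccl7 by 1.26 ± 0.20 and Cxcl11 by 1.88 ± 0.33. T cell markers were not called without radiation replicate 1 (0.34) or 3 (0.48). Cytokines and chemokines had 0.40 without radiation replicate 3.

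Other immune and stromal lists rose in part with radiation. Immune checkpoints had 6 of 13 higher (6 adjusted over the list alone), with Lgals9 at 0.74 ± 0.10 and Cd274, the PD-L1 gene, at 1.25 ± 0.37 (adjusted p = 0.040). Dendritic cell markers had 4 of 9 (5 adjusted over the list alone), including Cd86 (0.70 ± 0.13). NF-kB and TNF response genes had 5 of 17 higher and 1 lower (6 and 2 adjusted over the list alone), with Icam1 at 1.14 ± 0.19. Pyroptosis and necroptosis genes had 5 of 14 (8 adjusted over the list alone), with the cytokine gene Il18 at 1.43 ± 0.28. Medians of these lists were 0.67, 0.70, 0.26 and 0.40 in that order (camera, BH-adjusted p = 0.0046, 0.00056, 0.0046 and 0.00097, and adjusted p = 0.361, 0.222, 0.477 and 0.222 with an estimated correlation). Neutrophil markers had 2 of 14 higher (2 adjusted over the list alone), with a median of 0.61 (camera, adjusted p = 0.012, estimated 0.477). Csf3r, the receptor gene for the growth factor G-CSF, rose by 1.04 ± 0.19. Fibroblast and extracellular matrix genes had 2 of 22 higher (2 adjusted over the list alone), Bgn and Dpt, with a median of 0.26 (camera, adjusted p = 0.023, estimated 0.479). For mast cell, basophil and eosinophil markers the median was 0.60 (camera, adjusted p = 0.021, estimated 0.479), and of 7 members none passed edgeR's test (2 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Checkpoints had 0.22 without radiation replicate 1. Genes of the NF-kB and TNF response were not called without radiation replicate 3 (0.13). They had 0.14 without control replicate 2 and 0.42 without radiation replicate 2. Neutrophil markers were not called without control replicate 3 (0.46) or radiation replicate 3 (0.30). They had 1.07 without control replicate 1 and 0.97 without radiation replicate 2. Fibroblast and matrix genes were not called without control replicate 3 (0.20) or radiation replicate 2 (0.047). They had 0.43 and 0.41 without radiation replicate 1 or 3. Mast cell, basophil and eosinophil markers were not called without control replicate 1 (0.50) or radiation replicate 3 (0.52).

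Many genes for cell division and protein folding fell in irradiated tumours. Of the 32 proliferation genes, 18 fell (21 adjusted over the list alone), with a median log2 change of -0.28 (camera, adjusted p = 5.5e-13, estimated 0.246). Mki67, the gene of the Ki-67 antigen, had a change of -0.40 ± 0.09, Rrm2, a subunit of ribonucleotide reductase, -0.44 ± 0.08 and Pcna -0.34 ± 0.07. Among 36 DNA repair and damage signalling genes, 7 fell (8 adjusted over the list alone) and none rose (1 did adjusted over the list alone), with H2ax at -0.57 ± 0.11 and Ercc1 at -0.58 ± 0.12. Their median was -0.15 (camera, adjusted p = 0.00060, estimated 0.222). ER stress and chaperone genes had 14 of 24 lower (19 adjusted over the list alone) and a median of -0.35 (camera, adjusted p = 1.1e-10, estimated 0.222). Trib3, a pseudokinase gene of the ATF4 stress pathway, had -1.42 ± 0.18, adjusted p = 0.00097. Ddit3, the CHOP gene, had -0.98 ± 0.14 and Hspa5, the BiP chaperone gene, -0.62 ± 0.10. Of 11 heat shock genes 6 fell (8 adjusted over the list alone), with a median of -0.35 (camera, adjusted p = 7.4e-05, estimated 0.272). Hspa1a had -1.76 ± 0.31 and Hspa1b -0.99 ± 0.25, and these near-identical genes share 65.4% and 68.1% of their sequence with another locus. Cytosolic ribosomal protein genes had 7 of 24 lower (17 adjusted over the list alone), with a median of -0.30 (camera, adjusted p = 1.5e-07, estimated 0.372). Hypoxia and glycolysis genes had 1 higher and 3 of 23 lower (1 and 5 adjusted over the list alone), with Vegfa at -0.65 ± 0.14 and a median of -0.20 (camera, adjusted p = 0.0073, estimated 0.551). They were not called without radiation replicate 2 (-0.13) and had -0.31 without control replicate 1. Outside the lists, large falls were in Soat2 (-1.87 ± 0.28), which esterifies cholesterol, Cdsn (-2.08 ± 0.38), Angptl6 (-1.90 ± 0.36) and Car6 (-2.12 ± 0.62, adjusted p = 0.041).

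By camera, 22 of the 32 tested lists passed in radiation against control, 16 higher and 6 lower, and 2 of them also did with an estimated correlation. Single libraries moved the number of passing genes, which was 899 and 1007 without control replicate 1 or 2. It was 865 and 1153 without radiation replicate 1 or 3. With library totals as the only scaling, 1163 genes were higher and 576 lower, and with the gene length trend removed 910 were higher and 1301 lower.

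**Figure D2:**
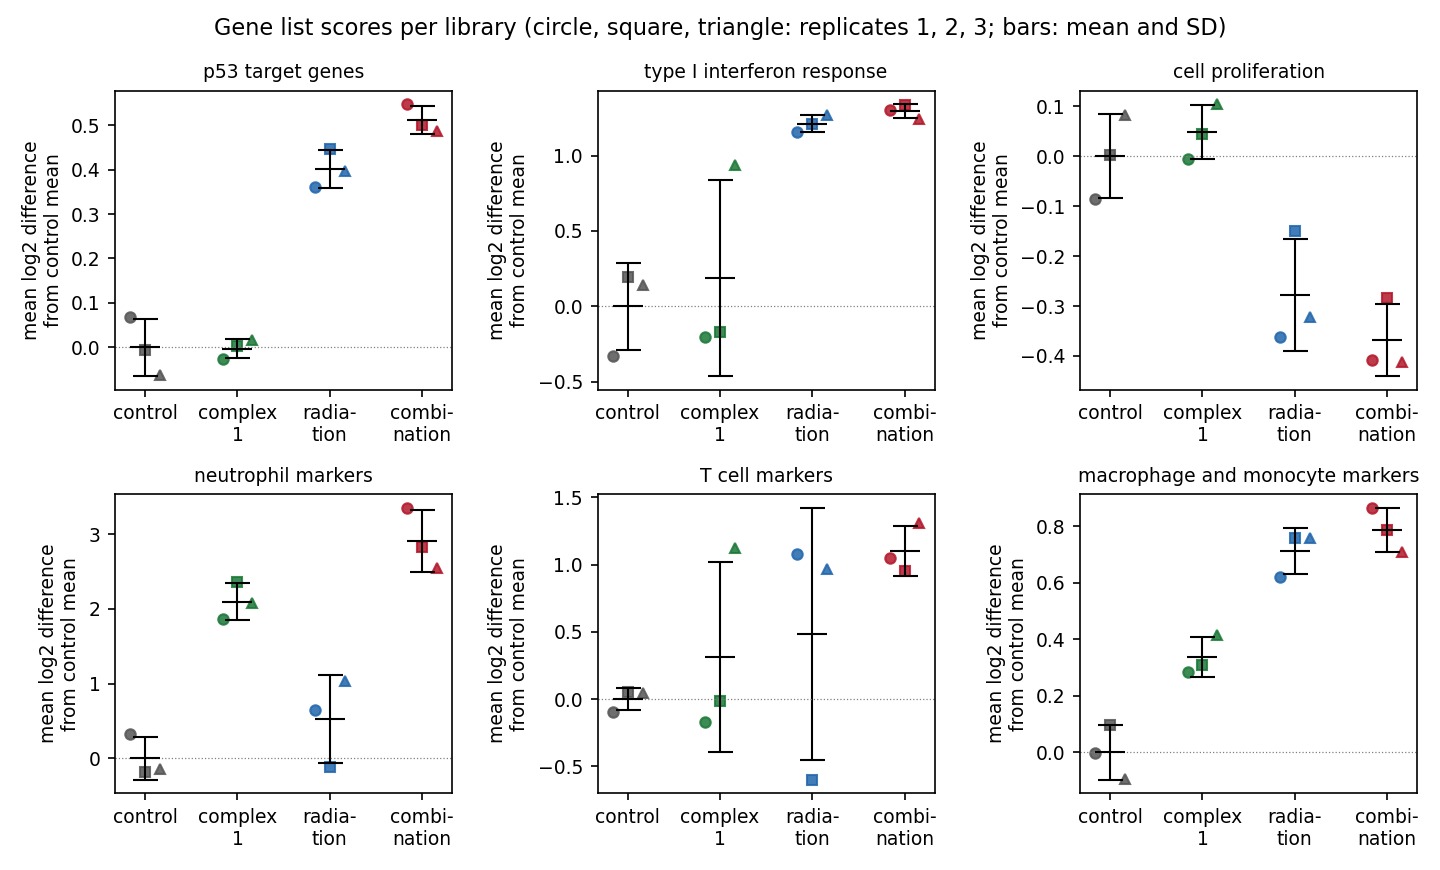
Score of 6 gene lists in each library, as the mean log2 difference of the list's genes from the control mean, with bars for the group mean and SD (n = 3) and symbols for replicates 1 to 3. The p53 target score is 0.362 to 0.548 in irradiated and -0.0620 to 0.0673 in unirradiated libraries, and neutrophil genes are highest in the combination.

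Complex 1 against control shows what the compound did without radiation. Some neutrophil markers and some inflammatory cytokine and chemokine genes rose. In total, 98 genes rose and 13 fell (edgeR quasi-likelihood, BH), and 1708 had an unadjusted p under 0.05. At least 2-fold changes were 44 rises and 2 falls. S100a8 and S100a9, which encode the subunits of calprotectin, an abundant protein of neutrophils, were among the largest. S100a9 rose from 7.59 ± 3.90 to 96.7 ± 41.3 FPKM (log2 3.63 ± 0.51, adjusted p = 0.0086; ENSMUSG00000056071, chromosome 3, 90599939 to 90603028, mm39). S100a8 rose from 2.07 ± 0.392 to 25.04 ± 14.6 (log2 3.55 ± 0.51, adjusted p = 0.010). Cxcl2, a chemokine that attracts neutrophils through the receptor Cxcr2, rose from 1.14 ± 0.321 to 14.8 ± 6.90 FPKM (log2 3.65 ± 0.47, adjusted p = 0.0073; ENSMUSG00000058427, chromosome 5, 91051730 to 91053797). Of the 14 neutrophil markers, 7 rose (14 adjusted over the list alone), with a median log2 change of 2.13 (camera, adjusted p = 8.8e-22, estimated 0.072). Inflammatory cytokines and chemokines had 5 of 22 higher (14 adjusted over the list alone) and a median of 1.05 (camera, adjusted p = 3.2e-14, estimated 0.104), which was 0.57 without Complex 1 replicate 3. Besides Cxcl2, Cxcl3 rose by 3.33 ± 0.59 and Il1b, interleukin 1 beta, by 2.13 ± 0.38. Slfn4, a gene of activated myeloid cells, rose by 2.25 ± 0.40 and Hcar2, a receptor gene for butyrate and niacin, by 2.16 ± 0.34.

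Macrophage markers shifted less than neutrophil markers with Complex 1. Macrophage and monocyte markers had 2 of 22 higher (12 adjusted over the list alone), Ms4a7 (0.74 ± 0.15) and Msr1 (0.44 ± 0.09), with a median of 0.35 (camera, adjusted p = 3.7e-08, estimated 0.074). In the pyroptosis and necroptosis list, 1 of 14 rose, Il1b (4 adjusted over the list alone), and the median was 0.30 (camera, adjusted p = 0.0021, estimated 0.258). This list was not called without Complex 1 replicate 3 (0.17). Several mitochondrially encoded genes also had higher levels. mt-Nd3 rose from 3.07 ± 1.03 to 12.9 ± 1.56 FPKM (log2 2.04 ± 0.26, adjusted p = 0.0073). Of the 10 in the list, 3 rose (3 adjusted over the list alone), mt-Atp6, mt-Co2 and mt-Co3, with changes of 1.29 ± 0.17, 1.00 ± 0.15 and 1.30 ± 0.19. Their list median was 0.13 (camera, adjusted p = 0.0021, estimated 0.616). It was 0.064 without control replicate 1 and 0.035 without Complex 1 replicate 1. Between 98.1% and 100% of the 31-base sequences of these 4 genes occur in another locus, so their counts are uncertain. The falls were led by Gpnmb, a glycoprotein gene of macrophages and melanocytes (-1.19 ± 0.18, adjusted p = 0.011), and H1f2, a linker histone gene (-1.12 ± 0.18, adjusted p = 0.014). Smaller falls were those of Zxdc (-0.62 ± 0.10), Dnajb4 (-0.61 ± 0.10), Zfand2a (-0.52 ± 0.09), Cpe (-0.50 ± 0.10), Jund (-0.45 ± 0.09) and Fam107b (-0.43 ± 0.08).

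Interferon and cytotoxic lists rested on Complex 1 replicate 3. Type I interferon genes had a median of 0.28 (camera, adjusted p = 0.039, estimated 0.768), and of 30 members none passed edgeR's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Without Complex 1 replicate 3 the median was -0.18 (camera, BH-adjusted p = 3.3e-06), and without control replicate 1 the test's direction turned, with a median of 0.12. For 23 interferon-gamma response genes the median was 0.51 (camera, adjusted p = 0.0040, estimated 0.653), with none passing edgeR's test (4 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2), and -0.21 without that replicate. Cytotoxic effectors (19 tested, median 0.45, camera, adjusted p = 0.017, estimated 0.653) had none passing edgeR's test (4 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2) and -0.075 without it. Nucleic acid sensing genes (16 tested, median 0.17, camera, adjusted p = 0.024, estimated 0.648) had none passing edgeR's test (3 at unadjusted p under 0.05, 2 adjusted over the list alone and 1 by DESeq2) and -0.032 without it. Without control replicate 1 camera called none of these last 3 lists, with medians of 0.36, 0.44 and 0.11. Without Complex 1 replicate 1 or 2, type I interferon genes had 0.50 and 0.48 and interferon-gamma genes 0.79 and 0.77. Nucleic acid sensing genes had 0.26 and 0.26 there and 0.25 without control replicate 3.

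Camera also called lists of which no member passed edgeR's test with Complex 1, and none of these was called with an estimated correlation. Heat shock genes had a median of -0.37 (camera, adjusted p = 3.7e-05, estimated 0.398; of 11, 7 at unadjusted p under 0.05, 7 adjusted over the list alone and 3 by DESeq2). ER stress and chaperone genes followed at -0.15 (camera, adjusted p = 9.3e-06, estimated 0.608; of 24, 8 at unadjusted p under 0.05, 2 adjusted over the list alone and 2 by DESeq2). Dendritic cell markers lay at 0.35 (camera, adjusted p = 0.0021, estimated 0.299; of 9, 4 at unadjusted p under 0.05, 2 adjusted over the list alone and 1 by DESeq2) and NF-kB and TNF response genes at 0.21 (camera, adjusted p = 0.0032, estimated 0.616; of 17, 5 at unadjusted p under 0.05, 2 adjusted over the list alone and 2 by DESeq2). Immune checkpoints had 0.30 (camera, adjusted p = 0.027, estimated 0.610; of 13, 0 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Endothelial markers had 0.37 (camera, adjusted p = 0.00032, estimated 0.610; of 17, 4 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2), and fibroblast and extracellular matrix genes 0.25 (camera, adjusted p = 0.036, estimated 0.648; of 22, 4 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Hypoxia and glycolysis genes had -0.13 (camera, adjusted p = 0.036, estimated 0.653; of 23, 3 at unadjusted p under 0.05, 0 adjusted over the list alone and 1 by DESeq2, against 2 higher at unadjusted p) and ribosomal protein genes -0.10 (camera, adjusted p = 0.0047, estimated 0.653; of 24, 1 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Several of these depended on single libraries. Checkpoint scores were 0.03, 0.15 and 0.66 in the Complex 1 replicates, and endothelial scores 0.46, 0.68 and -0.07. Checkpoints were not called without control replicate 1 (0.38) or 3 (0.40) or Complex 1 replicate 3 (0.064). They had 0.50 without Complex 1 replicate 1. Endothelial markers had 0.61 and 0.20 without control replicate 1 or 2. Fibroblast and matrix genes were not called without control replicate 3 (0.14) or Complex 1 replicate 3 (0.20). Ribosomal protein genes were not called without control replicate 1 (-0.041) or Complex 1 replicate 3 (-0.036). They had -0.15 without control replicate 3. Hypoxia and glycolysis genes were not called without control replicate 2 (-0.086) or 3 (-0.053) or Complex 1 replicate 1 (-0.12) or 2 (-0.044). They had -0.20 without control replicate 1 and -0.23 without Complex 1 replicate 3. ER stress and chaperone genes had -0.063 and -0.095 without control replicate 1 or 2. Dendritic cell markers had 0.57 and 0.13 without control replicate 1 or 3. Genes of the NF-kB and TNF response had 0.13 without Complex 1 replicate 3.

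By camera, 18 lists passed in Complex 1 against control, 14 higher and 4 lower, and none did with an estimated correlation. DESeq2 called 326 genes, 244 higher and 82 lower. The count of 111 genes rested on single libraries. It was 61, 4 and 70 without control replicate 1, 2 or 3. Without Complex 1 replicate 1, 2 or 3 it was 236, 25 and 57. No gene of those fixed for naming passed here: Cdkn1a had a change of -0.02 ± 0.13, adjusted p = 0.966.

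**Figure D3:**
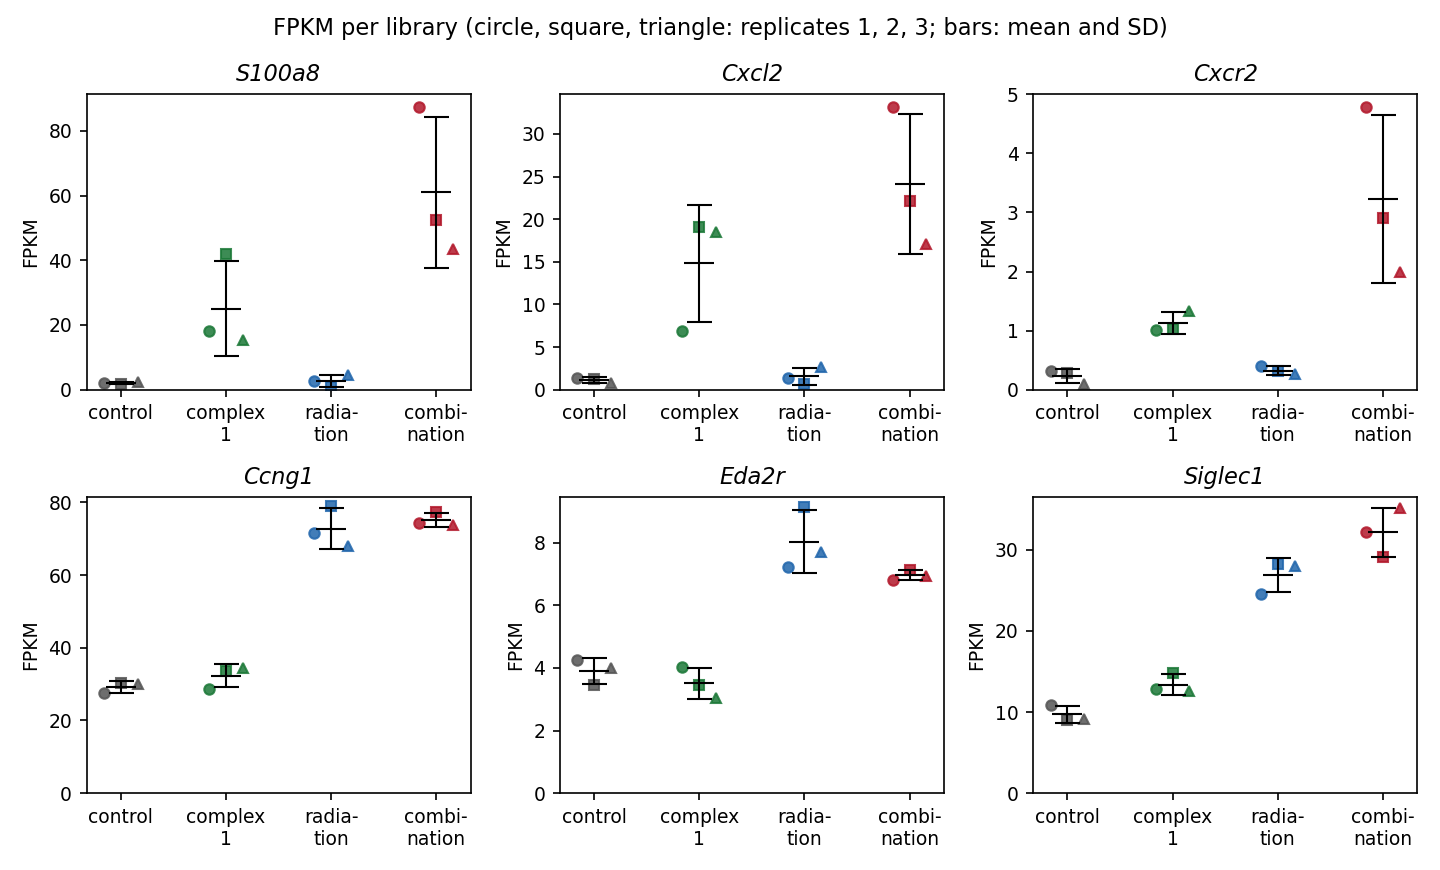
FPKM of 6 genes in each library, by group, with bars for the mean and SD (n = 3) and symbols for replicates 1 to 3. S100a8 has means of 2.07, 25.04, 2.66 and 60.9 FPKM, and Ccng1 29.2, 32.3, 72.8 and 75.1, in control, Complex 1, radiation and combination.

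Combination against control shows what both treatments did together. Members of the neutrophil, cytokine, interferon, cytotoxic effector and p53 lists rose, and members of the proliferation and ER stress lists fell. In total, 1620 genes rose and 1372 fell (edgeR quasi-likelihood, BH), and 4721 had an unadjusted p under 0.05. At least 2-fold changes were 506 rises and 44 falls. S100a8 rose from 2.07 ± 0.392 to 60.9 ± 23.2 FPKM (log2 4.83 ± 0.51, adjusted p = 9.6e-05) and S100a9 by 4.82 ± 0.51. Cxcl1 rose from 8.33 ± 3.70 to 144 ± 89.4 FPKM (log2 4.06 ± 0.53, adjusted p = 0.00029), Cxcl2 by 4.34 ± 0.47 and Cxcl5 by 4.46 ± 0.55. Saa3, an acute phase protein gene, rose by 4.39 ± 0.63, Slfn4 by 3.20 ± 0.41 and Il1b by 3.01 ± 0.39. All 14 neutrophil markers rose (14 adjusted over the list alone), with a median of 2.74 (camera, adjusted p = 7.1e-14, estimated 0.071). Inflammatory cytokines and chemokines had 20 of 22 higher (21 adjusted over the list alone), with Osm at 2.48 ± 0.25, Ccl2 at 1.66 ± 0.17 and a median of 2.21 (camera, adjusted p = 4.0e-17, estimated 0.064).

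Interferon and some lymphocyte genes rose in the combination. All 30 type I interferon response genes rose (30 adjusted over the list alone), with Oas2 at 1.44 ± 0.22, Mx1 at 1.99 ± 0.32 and a median of 1.19 (camera, adjusted p = 1.4e-17, estimated 0.202). Interferon-gamma response genes had 14 of 23 higher (22 adjusted over the list alone), with Cxcl10 at 2.05 ± 0.30, Cxcl9 at 1.00 ± 0.24, Nos2 at 2.60 ± 0.53 and a median of 1.13 (camera, adjusted p = 4.2e-09, estimated 0.325). Among nucleic acid sensing genes, 13 of 16 rose (13 adjusted over the list alone), with Sting1 at 0.66 ± 0.11 and a median of 0.77 (camera, adjusted p = 1.7e-07, estimated 0.181). Cytotoxic effectors had 15 of 19 higher (16 adjusted over the list alone), with Gzma at 2.46 ± 0.32, Gzmb at 2.36 ± 0.39, Prf1 at 2.09 ± 0.41, Ccl5 at 1.58 ± 0.41 and a median of 1.37 (camera, adjusted p = 3.5e-09, estimated 0.231). T cell markers had 7 of 17 higher (11 adjusted over the list alone), with Lck at 1.32 ± 0.24, Cd4 at 1.49 ± 0.40 and a median of 1.12 (camera, adjusted p = 2.7e-05, estimated 0.403). Cd8a had 0.81 ± 0.51 (adjusted p = 0.286) and did not pass. Immune checkpoints had 7 of 13 higher (10 adjusted over the list alone), with Havcr2, the TIM-3 gene, at 1.19 ± 0.24, Cd274 at 1.26 ± 0.37 and a median of 1.14 (camera, adjusted p = 0.00017, estimated 0.181). Of 5 regulatory T cell markers 2 rose (3 adjusted over the list alone), Il2ra (1.88 ± 0.36) and Ctla4 (1.24 ± 0.40), with a median of 0.89 (camera, adjusted p = 0.029, estimated 0.370). Foxp3 lay below the expression filter at 0.19 to 0.76 FPKM per library. MHC class I genes had 6 of 19 higher (8 adjusted over the list alone) and a median of 0.57 (camera, adjusted p = 3.9e-05, estimated 0.415). MHC class II genes had 2 of 10 (1 adjusted over the list alone), with Ctss at 1.15 ± 0.16 and a median of 0.46 (camera, adjusted p = 0.037, estimated 0.566). MHC class II genes were not called without control replicate 2 (0.43) or 3 (0.48) or combination replicate 2 (0.34). Regulatory T cell markers were not called without control replicate 1 (0.68) or combination replicate 1 (0.95).

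Myeloid markers and p53 targets rose too. Macrophage and monocyte markers had 15 of 22 higher (18 adjusted over the list alone), with Adgre1 at 1.53 ± 0.14, Ms4a7 at 1.45 ± 0.15 and a median of 0.80 (camera, adjusted p = 2.6e-11, estimated 0.030). Dendritic cell markers had 5 of 9 (5 adjusted over the list alone), with a median of 0.68 (camera, adjusted p = 0.00020, estimated 0.134). NF-kB and TNF response genes had 12 of 17 (13 adjusted over the list alone), with Birc3 at 0.95 ± 0.12, Icam1 at 1.38 ± 0.19 and a median of 0.83 (camera, adjusted p = 2.7e-08, estimated 0.181). Pyroptosis and necroptosis genes had 9 of 14 (10 adjusted over the list alone), with Il18 at 1.97 ± 0.27, Gsdmd at 0.60 ± 0.11 and a median of 0.56 (camera, adjusted p = 0.00015, estimated 0.120). Of the 26 p53 target genes, 15 rose (17 adjusted over the list alone), with Ccng1 at 1.31 ± 0.08, adjusted p = 1.8e-06, Phlda3 at 0.76 ± 0.09, Cdkn1a at 1.01 ± 0.13, Mdm2 at 0.51 ± 0.06, Bax at 0.64 ± 0.09 and Fas at 1.52 ± 0.25. Their median was 0.48 (camera, adjusted p = 3.5e-09, estimated 0.030). Mast cell, basophil and eosinophil markers had a median of 0.62 (camera, adjusted p = 0.039, estimated 0.512), with none of 7 passing edgeR's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). They were not called without control replicate 1 (0.41) or 2 (0.60) or combination replicate 3 (0.44).

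Falls in the combination covered division, repair and stress genes. Of the 32 proliferation genes, 23 fell (28 adjusted over the list alone), with Mki67 at -0.66 ± 0.09, Tpx2 at -0.51 ± 0.07 and a median of -0.39 (camera, adjusted p = 7.9e-15, estimated 0.181). DNA repair genes had 1 higher and 11 of 36 lower (2 and 11 adjusted over the list alone), with Ercc1 at -0.76 ± 0.12, Brca2 at -0.53 ± 0.09 and a median of -0.20 (camera, adjusted p = 0.00033, estimated 0.134). ER stress and chaperone genes had 13 of 24 lower (20 adjusted over the list alone), with Ddit3 at -1.08 ± 0.14, Trib3 at -1.41 ± 0.18 and a median of -0.34 (camera, adjusted p = 3.5e-09, estimated 0.181). Heat shock genes had 2 of 11 lower (2 adjusted over the list alone) and a median of -0.30 (camera, adjusted p = 0.015, estimated 0.415). Ribosomal protein genes had 10 of 24 lower (18 adjusted over the list alone) and a median of -0.32 (camera, adjusted p = 4.1e-07, estimated 0.325). Hypoxia and glycolysis genes had 2 higher and 8 of 23 lower (2 and 9 adjusted over the list alone), with Pfkfb3 at 1.11 ± 0.22, Vegfa at -0.70 ± 0.14 and a median of -0.27 (camera, adjusted p = 0.018, estimated 0.566). Heat shock genes were not called without control replicate 2 (-0.15) or combination replicate 2 (-0.24). Hypoxia and glycolysis genes were not called without control replicate 2 (-0.18) or 3 (-0.19). Mitochondrially encoded genes were not called by camera, and their median (-0.22) and mean (0.05) differed in sign. Large single falls were those of Cox6a2 (-3.15 ± 0.81), a muscle form of a cytochrome oxidase subunit, Cdsn (-2.20 ± 0.38), Angptl6 (-2.00 ± 0.36), Dmp1 (-1.86 ± 0.39) and Soat2 (-1.82 ± 0.28).

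By camera, 23 lists passed in combination against control, 17 higher and 6 lower, and 2 did with an estimated correlation, p53 targets and macrophage markers. With library totals as the only scaling 1947 genes were higher and 888 lower, with quantile normalisation 1204 and 1556, and with the length trend removed 1443 and 2234.

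Combination against radiation shows what Complex 1 added in irradiated tumours. Members of the neutrophil and the cytokine and chemokine lists rose. In total, 84 genes rose and 5 fell (edgeR quasi-likelihood, BH), and 1411 had an unadjusted p under 0.05. At least 2-fold changes were 59 rises and no falls. S100a8 rose from 2.66 ± 1.86 to 60.9 ± 23.2 FPKM (log2 4.50 ± 0.49, adjusted p = 0.0034; ENSMUSG00000056054, chromosome 3, 90576285 to 90577342) and S100a9 from 11.7 ± 9.08 to 222 ± 59.7 (log2 4.23 ± 0.49, adjusted p = 0.0034). Cxcr2, the receptor gene that neutrophils use to follow Cxcl1, Cxcl2 and Cxcl5, rose by 3.28 ± 0.38 (adjusted p = 0.0034). Of the 14 neutrophil markers, 9 rose (14 adjusted over the list alone), with a median of 1.97 (camera, adjusted p = 8.7e-27, estimated 0.039). Inflammatory cytokines and chemokines had 10 of 22 higher (13 adjusted over the list alone) and a median of 1.15 (camera, adjusted p = 1.3e-19, estimated 0.065). Cxcl2 rose by 3.89 ± 0.45, Cxcl1 by 3.30 ± 0.51, Cxcl5 by 3.36 ± 0.50 and Il1b by 2.68 ± 0.38. Saa3 rose by 3.76 ± 0.59 and Lcn2, a neutrophil granule and acute phase gene, by 2.91 ± 0.37. NF-kB and TNF response genes had 2 of 17 higher (9 adjusted over the list alone), including the NF-kB target Sod2 (0.57 ± 0.11), with a median of 0.28 (camera, adjusted p = 8.8e-10, estimated 0.372).

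Lymphocyte lists had positive medians that depended on radiation replicate 2, with none of their members passing edgeR's test. T cell markers had 0.47 (camera, adjusted p = 0.00027, estimated 0.774; of 17, 1 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2) and cytotoxic effectors 0.50 (camera, adjusted p = 6.6e-05, estimated 0.766; of 19, 1 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Immune checkpoints had 0.26 (camera, adjusted p = 0.033, estimated 0.766; of 13, 2 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2) and regulatory T cell markers 0.47 (camera, adjusted p = 0.033, estimated 0.766; of 5, 1 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). MHC class I genes had 0.14 (camera, adjusted p = 0.033, estimated 0.856; of 19, 1 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Heat shock genes had 0.14 (camera, adjusted p = 0.034, estimated 0.774; of 11, 2 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Proliferation genes had -0.09 (camera, adjusted p = 0.00031, estimated 0.774; of 32, 4 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). T cell scores in the radiation replicates were 1.08, -0.60 and 0.97. Without radiation replicate 2 camera called none of these lists, with medians of 0.16 for T cell markers, 0.25 for cytotoxic effectors, 0.16 for checkpoints, 0.16 for regulatory T cell markers, -0.031 for MHC class I, 0.07 for heat shock and -0.024 for proliferation genes. Checkpoints were not called either without radiation replicate 3 (0.33), combination replicate 1 (0.22) or combination replicate 3 (0.31). Regulatory T cell markers were not called without combination replicate 1 (0.40) or combination replicate 3 (0.34). MHC class I was not called without combination replicate 2 (0.11), nor heat shock genes without combination replicate 3 (-0.0035). Proliferation genes had -0.14 without radiation replicate 1. MHC class I genes had 0.27 without radiation replicate 3. Checkpoints had 0.41 without radiation replicate 1. Regulatory T cell markers had 0.80 without radiation replicate 1. The 5 genes that fell were Zc2hc1a (-0.52 ± 0.10, adjusted p = 0.023), Cplx2 (-0.50 ± 0.10), Mastl, a mitotic kinase gene (-0.45 ± 0.08), Tmem200a (-0.45 ± 0.09) and Tenm3 (-0.43 ± 0.08). Next to them, Trim24 had -0.32 ± 0.07, adjusted p = 0.054, Rgl1 -0.27 ± 0.06, adjusted p = 0.055 and Lxn -0.36 ± 0.08, adjusted p = 0.066 and did not pass.

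By camera, 10 lists passed in combination against radiation, 9 higher and 1 lower, and 1 did with an estimated correlation, neutrophil markers. Without radiation replicate 2, 4 lists passed. DESeq2 called 187 genes, 158 higher and 29 lower. The count of 89 genes was 25 and 39 without radiation replicate 1 or 2, and 41 and 41 without combination replicate 1 or 2. No gene of those fixed for naming passed here.

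Combination against Complex 1 shows what radiation added in tumours of mice given the compound. Members of the p53, type I interferon and cytotoxic effector lists rose, and members of the proliferation list fell. In total, 647 genes rose and 717 fell (edgeR quasi-likelihood, BH), and 3496 had an unadjusted p under 0.05. At least 2-fold changes were 130 rises and 22 falls. Ccng1 rose from 32.3 ± 3.14 to 75.1 ± 1.97 FPKM (log2 1.20 ± 0.08, adjusted p = 8.7e-06), Trp53inp1 by 1.52 ± 0.10 (adjusted p = 8.7e-06), Mdm2 by 0.59 ± 0.06, Cdkn1a by 1.03 ± 0.13, Bax by 0.54 ± 0.09 and Fas by 1.06 ± 0.24. Of the 26 p53 target genes, 16 rose (17 adjusted over the list alone), with a median of 0.42 (camera, adjusted p = 5.1e-15, estimated 0.0050). Type I interferon response genes had 23 of 30 higher (30 adjusted over the list alone), with Mx2 at 1.57 ± 0.29, Usp18 at 1.25 ± 0.24 and a median of 0.99 (camera, adjusted p = 9.0e-21, estimated 0.257). Nucleic acid sensing genes had 10 of 16 higher (13 adjusted over the list alone), with Ifih1 at 0.93 ± 0.19 and a median of 0.62 (camera, adjusted p = 7.6e-07, estimated 0.257). In the interferon-gamma response list, 1 of 23 rose, Cxcl10 by 1.05 ± 0.28, adjusted p = 0.032 (0 adjusted over the list alone), with a median of 0.70 (camera, adjusted p = 2.0e-07, estimated 0.408). Interferon-gamma genes had 0.41 and 1.45 without Complex 1 replicate 1 or 3.

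Granzymes gave large rises. Gzmf rose from 9.64 ± 2.03 to 88.0 ± 15.7 FPKM against 28.2 ± 30.9 in control (log2 3.18 ± 0.76, adjusted p = 0.019; ENSMUSG00000015441, chromosome 14, 56442720 to 56448874). Gzmg rose by 3.09 ± 0.81, Gzmd by 2.81 ± 0.67 and Gzmc by 2.07 ± 0.49. Gzme rose from 3.58 ± 1.39 to 28.8 ± 4.60 FPKM (adjusted p = 0.013). These lie in 1 gene family, and Gzmd, Gzme and Gzmg share 33.8% to 42.1% of their sequence with another locus. Cytotoxic effectors had 9 of 19 higher (11 adjusted over the list alone), with Prf1 at 1.86 ± 0.41, Gzmb at 1.67 ± 0.37 and a median of 0.93 (camera, adjusted p = 8.6e-09, estimated 0.297). Macrophage and monocyte markers had 9 of 22 (13 adjusted over the list alone), with Adgre1 at 1.12 ± 0.13 and a median of 0.49 (camera, adjusted p = 1.3e-07, estimated 0.069). Inflammatory cytokines and chemokines had 12 of 22 (13 adjusted over the list alone), with Cxcl1 at 2.70 ± 0.49, Cxcl5 at 2.55 ± 0.47, Ccl8 at 1.84 ± 0.29 and a median of 0.97 (camera, adjusted p = 1.6e-10, estimated 0.159). Neutrophil markers had 2 of 14 (5 adjusted over the list alone), with Cxcr2 at 1.49 ± 0.33 and a median of 0.78 (camera, adjusted p = 0.00065, estimated 0.323). NF-kB and TNF response genes had 9 of 17 (11 adjusted over the list alone), with Nfkbiz at 0.74 ± 0.14 and a median of 0.52 (camera, adjusted p = 1.2e-07, estimated 0.257). Immune checkpoints (3 of 13, 4 adjusted over the list alone), regulatory T cell markers (2 of 5, 2 adjusted over the list alone), dendritic cell markers (2 of 9, 2 adjusted over the list alone) and pyroptosis genes (2 of 14, 2 adjusted over the list alone) also had members that rose. Their medians were 0.62, 0.56, 0.27 and 0.30 (camera, BH-adjusted p = 0.0019, 0.014, 0.018 and 0.011, and adjusted p = 0.297, 0.323, 0.297 and 0.279 with an estimated correlation). T cell markers had a median of 0.70 (camera, adjusted p = 0.00019, estimated 0.439), with none of 17 passing edgeR's test (6 at unadjusted p under 0.05, 0 adjusted over the list alone and 2 by DESeq2), and MHC class I genes 0.43 (camera, adjusted p = 6.2e-05, estimated 0.433), with none of 19 passing (3 at unadjusted p under 0.05, 0 adjusted over the list alone and 1 by DESeq2). Without Complex 1 replicate 3, cytotoxic effectors had 1.56, regulatory T cell markers 1.05 and T cell markers 1.16. Checkpoints had 0.34, 0.37 and 1.05 without Complex 1 replicate 1, 2 or 3. Dendritic cell markers were not called without Complex 1 replicate 1 (0.17) or combination replicate 1 (0.20). They had 0.41 without combination replicate 3. Pyroptosis and necroptosis genes had 0.18 without Complex 1 replicate 1. MHC class I genes had 0.22 and 0.75 without Complex 1 replicate 1 or 3.

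Proliferation genes fell here in 27 of 32 cases (31 adjusted over the list alone), with Mki67 at -0.63 ± 0.09, Mcm7, a subunit of the replicative helicase, at -0.48 ± 0.07 and a median of -0.44 (camera, adjusted p = 2.8e-23, estimated 0.159). DNA repair genes had 13 of 36 lower (16 adjusted over the list alone, with 1 higher), with Brca2 at -0.55 ± 0.09 and a median of -0.25 (camera, adjusted p = 7.6e-07, estimated 0.069). ER stress and chaperone genes had 5 of 24 lower (7 adjusted over the list alone), with Trib3 at -1.26 ± 0.18 and a median of -0.21 (camera, adjusted p = 1.2e-05, estimated 0.323). Ribosomal protein genes had 2 of 24 lower (2 adjusted over the list alone), with a median of -0.23 (camera, adjusted p = 2.1e-05, estimated 0.415). Mitochondrially encoded genes had a median of -0.32 (camera, adjusted p = 0.0013, estimated 0.432), with none of 10 passing edgeR's test (5 at unadjusted p under 0.05, 5 adjusted over the list alone and 2 by DESeq2). Ribosomal protein genes had -0.11 without combination replicate 3. Mitochondrially encoded genes had -0.19 without Complex 1 replicate 1. Large falls were in Cdsn (-1.88 ± 0.38), Angptl6 (-1.70 ± 0.36), Soat2 (-1.64 ± 0.28), P2rx3 (-1.60 ± 0.41) and Plet1 (-1.59 ± 0.44). By camera, 20 lists passed, 15 higher and 5 lower, and 1 did with an estimated correlation, p53 targets. The count of 1364 genes was 652 and 582 without Complex 1 replicate 1 or 2. It was 640, 880 and 801 without combination replicate 1, 2 or 3. Which direction had more genes depended on the setting. With library totals as the only scaling 782 were higher and 621 lower, with median-ratio scaling 718 and 685, and with the length trend removed 595 and 934. Without Complex 1 replicate 3 they were 1033 and 851.

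The 2 by 2 design gives each treatment's effect over all 12 libraries. For radiation, 6 irradiated against 6 unirradiated libraries, 1821 genes rose and 1802 fell, with 5272 at unadjusted p under 0.05 (edgeR quasi-likelihood, BH). The smallest p-values among rises were those of Trp53inp1 (1.58 ± 0.07, adjusted p = 6.9e-08), Ccng1 (1.24 ± 0.06), Siglec1, a sialic acid receptor gene of macrophages (1.34 ± 0.07), Inka2 (1.53 ± 0.10) and Ephx1 (0.96 ± 0.06). Among falls they were those of Hirip3 (-0.58 ± 0.05), Anp32e (-0.54 ± 0.05), Tbc1d31 (-0.70 ± 0.06), Stmn1 (-0.68 ± 0.06) and Spc25 (-0.57 ± 0.05), of which Anp32e and Hirip3 encode histone chaperones. Camera called 22 lists, 15 higher and 7 lower, of which p53 targets (17 of 26 rose, 17 adjusted over the list alone, median 0.40, camera, adjusted p = 5.1e-11, estimated 0.015) and macrophage markers (16 of 22 rose, 16 adjusted over the list alone, median 0.59, camera, adjusted p = 3.1e-10, estimated 0.039) held. Of the 32 proliferation genes, 31 fell (31 adjusted over the list alone), with a median of -0.35 (camera, adjusted p = 1.0e-18, estimated 0.194). Oxidative phosphorylation genes had 2 of 22 lower (2 adjusted over the list alone) and a median of -0.07 (camera, adjusted p = 0.031, estimated 0.568), and camera called them in no other comparison. They were not called without Complex 1 replicate 2 (-0.065), radiation replicate 1 (-0.037) or combination replicate 3 (-0.030). Calls of the hypoxia, heat shock and mast cell lists also ended without single libraries. Of the genes fixed for naming, those passing were also Mdm2 (0.54 ± 0.04), Cdkn1a (0.85 ± 0.09), Bax (0.52 ± 0.06), Fas (1.03 ± 0.17), Cxcl9 (0.75 ± 0.17), Cxcl10 (1.53 ± 0.20), Ccl5 (1.09 ± 0.29), Gzmb (1.73 ± 0.27), Prf1 (1.69 ± 0.29), Cd4 (0.93 ± 0.28), Cd274 (0.94 ± 0.26), Sting1 (0.44 ± 0.07) and Mki67 (-0.52 ± 0.07). With the length trend removed, 1575 genes were higher and 2453 lower, and with library totals as the only scaling 2125 and 1437.

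For Complex 1, 6 libraries with the compound against 6 without, 309 genes rose and 70 fell, with 2421 at unadjusted p under 0.05 (edgeR quasi-likelihood, BH). All 14 neutrophil markers rose (14 adjusted over the list alone), with a median of 2.04 (camera, adjusted p = 2.1e-26, estimated 0.040). The smallest p-values were those of Cxcl2 (3.77 ± 0.33, adjusted p = 0.00012), S100a8 (4.03 ± 0.35), S100a9 (3.93 ± 0.35), Cxcr2 (2.74 ± 0.28) and Csf3r (1.22 ± 0.13) among rises. Among falls they were those of Pja2 (-0.30 ± 0.05, adjusted p = 0.0036), Tmem200a (-0.42 ± 0.06), Tenm3 (-0.37 ± 0.06), Gpnmb (-0.79 ± 0.12) and Cplx2 (-0.43 ± 0.07). Inflammatory cytokines and chemokines had 12 of 22 higher (18 adjusted over the list alone) and a median of 1.11 (camera, adjusted p = 3.9e-20, estimated 0.061), which was 0.73 without Complex 1 replicate 3. Camera called 14 lists, 12 higher and 2 lower, and neutrophil markers alone held with an estimated correlation. Calls of the pyroptosis, MHC class I, T cell, checkpoint, endothelial and ribosomal protein lists ended when single libraries were left out. Interferon-gamma response genes had a median of 0.27 (camera, adjusted p = 0.011, estimated 0.815), which was -0.046 without Complex 1 replicate 3. The list was not called without control replicate 1 (0.20) or radiation replicate 2 (0.15) either. Of its members, 1 rose (1 adjusted over the list alone). Mitochondrially encoded genes were not called, and their median (-0.15) and mean (0.15) differed in sign. DESeq2 called 667 genes, 462 higher and 205 lower, and with the length trend removed 231 were higher and 103 lower. The count of 379 genes was 200 without control replicate 2 and 218 without radiation replicate 1. It was 608 and 215 without Complex 1 replicate 1 or 2, and 211 and 223 without combination replicate 1 or 2.

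The genes that passed overlapped between comparisons. Radiation against control and combination against Complex 1, which share no library, had 437 genes higher in both and 411 lower in both. Independent lists would give 47.8 and 42.0. Their log2 changes correlated at 0.484 across genes. Complex 1 against control and combination against radiation, which also share no library, had 40 higher in both (0.602 for independent lists) and none lower in both (0.00476), with a correlation of 0.354. Complex 1 against control and radiation against control had 47 higher in both (7.24) and 7 lower in both (0.761). These share the control libraries, and in 20 simulations of unchanged groups against those controls no gene was called in both. The correlation was 0.413 against 0.492 ± 0.0176 simulated, and the covariance 0.0679 against 0.0394 ± 0.00253, a difference of 0.0285. The 3 control libraries cannot be split so that each part keeps a pair, so part of the excess may come from the shared controls. Genes are not independent replicates in these correlations.

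The interaction tests whether the combination departs from the sum of the single effects on the log2 scale. No gene passed edgeR's quasi-likelihood test (smallest BH-adjusted p = 0.939), with 601 at unadjusted p under 0.05 and 6 by DESeq2, 5 higher and 1 lower. The steps of S100a8 with Complex 1, 3.55 ± 0.51 without and 4.50 ± 0.49 with radiation, therefore were not shown to differ, nor were those of Cxcl10 with radiation, 2.01 ± 0.30 without and 1.05 ± 0.28 with the compound. Camera called 9 lists, 5 higher and 4 lower than the sum, and none held with an estimated correlation. Metal response and platinum transport genes were called in this comparison alone (7 tested, median 0.23, camera, adjusted p = 0.0036, estimated 0.229), with none passing edgeR's test (0 at unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2). Metal response genes had 0.42 without radiation replicate 3 and 0.41 without combination replicate 3. There the median and mean differed in sign for MHC class I genes (-0.02 and 0.01) and T cell markers (-0.06 and 0.02), and for checkpoints (-0.09 and -0.12) camera's direction was the opposite one; none of these was called.

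Among lists that camera called in no comparison, combination against control gave medians of 0.17 for pro-apoptotic genes, 0.03 for NRF2 and antioxidant genes, -0.08 for TGF-beta response and mesenchymal regulators and 0.03 for immediate early genes. In the same order radiation against control gave 0.14, -0.04, -0.04 and -0.06. Means were of the other sign for the TGF-beta list, 0.06 and 0.01, and for the NRF2 list in radiation against control, 0.07. B and plasma cell, epithelial, skeletal muscle and erythroid markers had 4 tested members each, adipocyte markers 3 and keratinocyte markers 2, too few for a list test. Both keratinocyte markers were lower by DESeq2 in radiation and in combination against control, with mean scores of -0.44 in Complex 1, -0.77 in radiation and -0.77 in combination libraries. Besides Cd8a, the tested genes among those fixed for naming that passed in none of the 8 comparisons had these changes in combination against control: Ifng 1.36 ± 0.59, Pdcd1 0.91 ± 0.38, Cgas 0.05 ± 0.10, H2-K1 0.18 ± 0.17, B2m 0.17 ± 0.12, Calr -0.14 ± 0.10, Hmgb1 -0.25 ± 0.16, Gpx4 -0.17 ± 0.09, Slc7a11 0.08 ± 0.30, Mt1 0.33 ± 0.21 and Mt2 0.56 ± 0.25.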

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

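The interaction of radiation and Complex 1 was a planned test, and the counts over other splits of the libraries were chosen as tests only after the results were seen. For 9 gene lists camera with its preset correlation put the log2 change of the combination above or below the sum of the single changes, but none of them was called with an estimated correlation or by fry. Above the sum were heat shock genes (median difference 0.43), metal response and platinum transport genes (0.23), ER stress and chaperone genes (0.15), NF-kB and TNF response genes (0.12) and p53 targets (0.079). Below it were mitochondrially encoded genes (-0.52), endothelial markers (-0.36), macrophage and monocyte markers (-0.31) and proliferation genes (-0.14). Adjusted p values with an estimated correlation were 0.229, 0.229, 0.645, 0.679, 0.326, 0.463, 0.645, 0.229 and 0.645 in that order. The p53 targets were not called without control replicate 1 (0.073) or radiation replicate 1 (0.092). They had 0.12 without Complex 1 replicate 3 and 0.13 without combination replicate 3. Genes of the NF-kB and TNF response were not called without radiation replicate 2 (0.095) or combination replicate 1 (0.055). They had 0.18 without Complex 1 replicate 1 and 0.23 without radiation replicate 3. ER stress and chaperone genes had 0.058, 0.088 and 0.23 without control replicate 1, 2 or 3 and 0.097 without Complex 1 replicate 3. Endothelial markers had -0.56 and -0.20 without control replicate 1 or 2 and -0.20 and -0.60 without Complex 1 replicate 2 or 3. Proliferation genes had -0.083 without control replicate 1 and -0.069 without radiation replicate 2. Metal response genes had 0.42 without radiation replicate 3 and 0.41 without combination replicate 3. Mitochondrially encoded genes had -0.34 without radiation replicate 2.

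Other splits of the same libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many calls. The real count and the highest other were 111 and 35 for Complex 1 against control, 1810 and 0 for radiation against control, 2992 and 0 for combination against control, 89 and 60 for combination against radiation, and 1364 and 0 for combination against Complex 1. For the effect of radiation over all 12 libraries, 1 of 100 splits, the real one, gave 3623 calls and the highest other 85. For that of Complex 1, 1 of 100 gave 379 and the highest other 94. Those splits mix the treatments, so libraries were also exchanged only within the levels of the other treatment. There 1 of 100 splits gave as many for each, again the real one. The highest others were 412 for radiation and 56 for Complex 1, a share of 0.01 if libraries are independent. For the interaction the count is 0, so all 100 splits give at least as many and say nothing about it. The highest of them gave 379 calls, which points to a structure of the samples: its 2 sides held 1 and 5 of the irradiated libraries, and 2 and 4 of those with Complex 1.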

How the results depend on the processing

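Alternatives chosen only after the data were seen were DESeq2, limma on FPKM, library totals only, protein-coding nuclear genes only, leaving out Complex 1 replicate 3 and radiation replicate 2 together, and removal of the length trend. Over all alternatives, those fixed beforehand and left-out libraries included, no gene that the rule named and that passed changed direction. Apart from fixed genes, these were picked by change or p in these libraries, so reversals were unlikely. Of their values, 5226 kept their side of the threshold and 498 did not. Among lists, over the same range, 1986 kept it, 340 lost it (129 with an estimated correlation and 75 with fry) and 14 turned direction, 7 of them without the 2 libraries left out together.

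Without the expression filter, 803 genes passed in Complex 1 against control, 529 in combination against radiation, 2285 in combination against Complex 1, 1262 for Complex 1 over all libraries and 163 in the interaction. That fit took the spread of 31727 genes as 1 common trend (infinite prior degrees of freedom, against 5.07), and 717 of the 803 and 151 of the 163 calls were among the 13668 genes tested otherwise. DESeq2 gave 326, 187 and 667 for Complex 1 against control, combination against radiation and Complex 1 over all libraries, and 6 for the interaction. Protein-coding nuclear genes alone gave 59, 46 and 227 in the first 3 of these, with fewer genes tested. Without Complex 1 replicate 3 and radiation replicate 2 together the counts were 66 in Complex 1 against control, 2155 in combination against Complex 1 and 242 for Complex 1 over all libraries. Complex 1 against control had 56 with quantile normalisation and 45 with only its groups in the fit. For these the cause was not tested.

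Leaving out 1 library at a time gave 4 to 236 genes in Complex 1 against control, 865 to 1678 in radiation against control, 2076 to 2771 in combination against control, 25 to 72 in combination against radiation and 582 to 1884 in combination against Complex 1. Radiation over all libraries had 2820 to 3805, Complex 1 200 to 608 and the interaction 0. The lowest count for Complex 1 against control, 4, came without control replicate 2, the library with Xist near 0.

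Lists called with an estimated correlation numbered 0 in Complex 1 against control, 2 in radiation against control, 2 in combination against control, 1 in combination against radiation, 1 in combination against Complex 1, 2 for radiation and 1 for Complex 1 over all libraries, and 0 in the interaction. With fry they numbered 3 in Complex 1 against control, 13 in radiation against control, 2 in combination against radiation, 9 in combination against Complex 1, 3 for Complex 1 over all libraries and 0 in the interaction. A pseudocount of 0.1 with limma gave 6 in combination against radiation. In the interaction, 17 lists were called with no filter and 14 without the 2 libraries left out together. Leaving out 1 library gave 12 to 24 lists in Complex 1 against control, 4 to 14 in combination against radiation (4 without radiation replicate 2) and 10 to 19 in the interaction. The interaction had 17, 14 and 19 without Complex 1 replicate 1, 2 or 3. It had 19 without radiation replicate 3 and 14 without combination replicate 2.

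Directions turned in the interferon and T cell lists when libraries were left out, and in these the libraries left out are the cause. In Complex 1 against control, medians over the left-out libraries ran from -0.18 to 0.50 for type I interferon genes, -0.21 to 0.79 for interferon-gamma genes, -0.075 to 0.66 for cytotoxic effectors and -0.032 to 0.26 for nucleic acid sensing, each lowest without Complex 1 replicate 3. With radiation replicate 2 left out too, the first 3 were -0.18, -0.21 and -0.080. Without control replicate 1 the type I interferon list had a median of 0.12 with a test in the lower direction. In combination against radiation, MHC class I genes ran from -0.031 (without radiation replicate 2) to 0.27, with -0.027 without both. Over all libraries, the Complex 1 effect on interferon-gamma genes ran from -0.046 (without Complex 1 replicate 3) to 0.40, with -0.19 without both, and without both MHC class I had -0.052 and T cell markers -0.026.

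The replicate numbers do not pair the libraries: 4 of 18 pairs with the same number correlated above 0.1 in their deviations (-0.204 to 0.164), and 4 of 12 libraries correlated best with their own number. A replicate block gave 87, 1894, 3072, 78 and 1518 genes in the pairwise comparisons, in the order of the leave-outs above, 3648 for radiation, 364 for Complex 1 and 0 for the interaction, within 1.5 times of the counts without it. Depth limits genes near the floor of 0.0785 to 0.0961 FPKM, such as Ifnb1, with a lowest level of 0.07.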

Other observations

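The KEGG pathways and all tests in this part were chosen only after the results were seen. For radiation over all 12 libraries camera called 80 of 288 pathways higher and 33 lower, and for Complex 1 54 and 8, but none held with an estimated correlation.

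Some neutrophil genes rose with Complex 1 both in tumours with and in tumours without radiation. More blood left in the tissue would bring globin RNA of red cells. The 4 tested erythroid genes had a median log2 change of -0.77 against 2.04 for the neutrophil list. All are mostly shared globins with uncertain counts. Their mean scores were 0.20 ± 1.02 with Complex 1 alone, 0.55 ± 1.11 with radiation and -0.88 ± 0.39 with both. Blood richer in neutrophils need not raise them, so blood stays open. Shared copies or gene length would need a loss of the rise in little-shared genes after removal of the length trend, and the median of 11 such genes of 14 was 1.85. More neutrophils in the tumours stay a hypothesis, since the labels record no batch and bulk RNA does not show which cells made these transcripts.

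Genes with near-identical copies had slightly higher values with Complex 1. Of 967 tested genes with at least 50% of their sequence in another locus, 92 rose and 2 fell, with a median log2 change of 0.13 over all libraries. With radiation the same genes went the other way: 38 rose and 108 fell, with a median of -0.12, and a median difference of -0.165 (-0.189 to -0.145) from length-matched genes of any type with no shared sequence. For Complex 1, gene length as the cause stays undecided. Length-matched protein-coding genes with no shared sequence had a median of 0.0766 (bootstrap interval 0.0686 to 0.0814), above 0.0647, a bound set for length at 50% of the copies' median. Length-matched genes of any type with no shared sequence had 0.0329 (0.0252 to 0.0391), below it. Sharing stays undecided too: the copies' median difference was 0.0967 (0.0726 to 0.132) from genes of any type and 0.0498 (0.0283 to 0.0791) from protein-coding ones, against bounds of 0.1 for it and 0.05 against it. The pattern includes mitochondrial genes: of 7 mostly shared ones 5 rose, and of 6 others 1 did, mt-Atp8, while the abundant mt-Co1 (63.9% shared) had a log2 change of -0.27, so the rises need not reflect more mitochondrial RNA.

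Complex 1 replicate 3 had high interferon and T cell genes for its group. A mislabelled tumour from inside the field would carry the p53 response. The replicate's p53 target score was 0.0153, against 0.362 to 0.548 in the 6 irradiated and -0.0620 to 0.0673 in the unirradiated libraries. Outside the field the response may be absent, so that case stays open. A swap with radiation replicate 2, lowest of its group in T cell score, would need an unirradiated p53 score there, and it was 0.448. A difference between tumours in immune infiltration was not tested. No test here addressed why control replicate 2 had Xist near 0 and Y-linked counts.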
